A study of Mytilus edulis with 40 samples.

How the data were processed

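Digestive gland RNA of 40 adult Mytilus edulis was measured on Agilent 1-colour arrays, 1 array per mussel, with 4 mussels in each of 10 groups (2 sexes by 5 treatments). Per the labels' protocols, water was held at 11.24 °C and renewed with its treatment 2 times a week, controls received the ethanol carrier at 0.004%, and Cy3-labelled cRNA was made from 200 ng of RNA. Per the file headers, the authors scanned the arrays with Agilent Feature Extraction 11.5.1.1, which gave each spot's processed signal, a linear intensity with the background subtracted within the array and no scaling between arrays. The files hold 61657 probes with 1 spot each and no saturated spot. They also list control spots, which were left out: 1319 on every male array, 661 for female control replicate 4 and 0 on the other female arrays. This difference followed sex also on the slide that held both sexes, and its reason was not tested. The scanning software's spatial and background settings beyond its protocol name are not given in the sources used here.

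The authors' deposited value table holds linear intensity as well. Set against the scanner values, each of its columns keeps the rank order of that array's processed signal, with a rank correlation of at least 0.999992. Its columns share the mean of the sorted processed signals of the 20 arrays of the same sex to within a median of 0.128%. Column medians ran from 13.7 to 13.8 in females and from 12.5 to 12.7 in males. Females and males were thus quantile normalized separately, which the labels do not state, and the table was used as an alternative within the sexes only. No centring or ratio was found in it.

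From the scanner values, log2 of the processed signal minus each array's 75th percentile was computed. Since under 50% of probes were well above background on most arrays, the percentile was taken over the 8005 probes that were well above background on all 40 arrays. Among the tested probes 111 spots flagged as outliers by the scanning software were left out. Probes had to be well above background on at least 4 arrays, which left 34730. The 75th percentile of the raw processed signal ran from 28.6 to 239 between arrays, so arrays differ in how far dim probes rise above background.

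Groups were compared with limma 3.58.1 in R 4.3.3, in a single fit of 10 group means to all 40 arrays, with moderated variances (3.12 prior degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. The comparisons were each treatment against control over both sexes and within each sex, females against males averaged over treatments, the interaction of sex and treatment as a moderated F test, the doses of each compound and the higher doses of the compounds. All treatments of a sex share the same control mussels, so a deviation of these controls enters each of their comparisons. The least-squares step was tested on simulated data with 200 probes changed by known amounts. Values were drawn as independent normal values around each probe's mean over all 40 arrays, with its residual SD. A probe that was not well above background on any array of a group has only a bound there. Its fold is given as at least the bright group's mean over a dim-group mean in which each array contributes the higher of the probe's own value and the lowest signal well above background. This bound covers the dim signal only. It allows for no spread between mussels and is not a confidence limit on the group difference.

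The probe columns hold contig names of a transcript assembly and no gene names, and 0 probe or contig names matched the reference table of gene names. The 22 gene lists therefore matched 0 probes and were not tested, among them egg and sperm genes, detoxification, heat shock and estrogen receptor lists. The rule for named probes then took the 2 highest and 2 lowest probes past the threshold in each comparison of a treatment or of the sexes, and where fewer passed, those with the smallest unadjusted p, described as not passing. A contig was named by its first such probe. This rule, the grouping, the tests of the comparisons and the alternatives were fixed before the data were examined, except where an alternative or a further test is said to have been chosen later.

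The alternatives were normexp background correction with an offset of 50, quantile normalization, the authors' table, no filter, probes well above background on all 40 arrays, array weights, slide as a block, replicate number as a block, same-numbered females and males as a random block, only the groups compared, and leaving out each array. For the sexes the replicate block was a term for each same-numbered female and male of a treatment. Normexp was planned on the mean signal. The median signal and median background took its place because the mean signal was not among the columns used here. Chosen after seeing the data were the percentile over all probes, leaving out the 2 arrays with under 30% of probes well above background, and values within slides. The set of 8005 probes behind the percentile of the main fit was chosen then too. The plan named the percentile without a set of probes, so the main scaling was not fully fixed beforehand. The arrays lay on 5 slides of 8, read in 3 scan sessions. Slides 1 and 2 held females only, slide 3 held 4 females and 4 males, and slides 4 and 5 held males only. Slides 1 to 3 were read in session 1, slide 4 in session 2 and slide 5 in session 3, so session adds nothing to slide. A slide effect passed the threshold for 9 probes in females and 63 in males.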

Results

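Gene expression was measured in the digestive gland, the organ of food processing and detoxification, of 40 adult blue mussels (Mytilus edulis) after 39 days of exposure. Females and males were kept in control water, in 5 or 50 ng/L of 17-alpha-ethinylestradiol (EE2, the synthetic estrogen of contraceptive pills) or in 1 or 100 µg/L of 4-nonylphenol (4NP, a breakdown product of surfactants that binds vertebrate estrogen receptors). Each of the 10 combinations of sex and treatment held 4 mussels, which per the series' design text came from separate tanks. RNA of each mussel was hybridised to its own array of 61657 probes, which stand for 39950 assembled contigs. The probes carry contig numbers and no gene names, so probes and contigs are named by those numbers, and none of the 22 gene lists fixed for this tissue could be tested.

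Between 16.6% and 53.3% of the probes were well above background on an array, with a median of 42.1% in females and 40.3% in males. Male control replicate 3, with 16.6%, and the male 100 µg/L 4NP replicate 1, with 25.5%, lay below the other 38 arrays, which started at 31.6%. The analysis covered the 34730 probes that were well above background on at least 4 arrays, from 23021 contigs. The correlation of log2 levels between mussels of the same group had a median of 0.795 over all tested probes, and between mussels of different groups of the same sex a median of 0.803. These are correlations across probes, which are not independent replicates. The median residual SD between mussels of a group was 0.82 log2 units. Where a contig had 2 tested probes, the deviations of the mussels from their group means correlated between the probes with a median of 0.787 over 11163 contigs, against 0.031 for random pairs of probes.

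**Figure D1:**
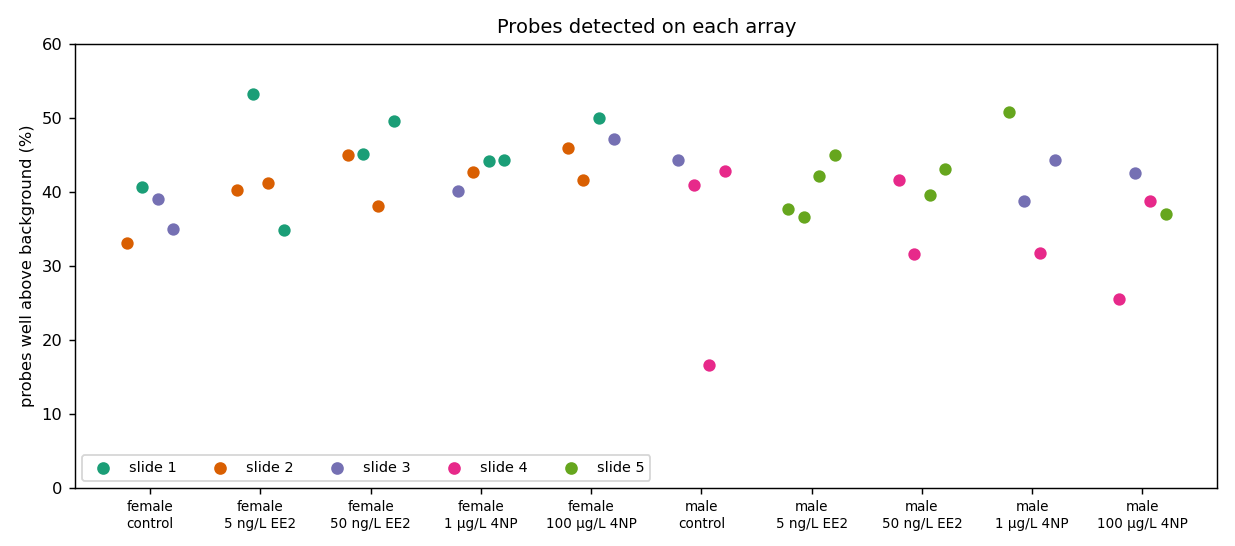
Percent of probes well above background (vertical axis) on each of the 40 arrays, by sex and treatment (horizontal axis), with the colour giving the slide. The lowest points are male control replicate 3 at 16.6% and male 100 µg/L 4NP replicate 1 at 25.5%.

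Females and males were compared to ask which transcripts differ by sex in this organ. Averaged over the 5 treatments, 27 probes differed between 20 females and 20 males at an adjusted p under 0.05 in limma, 23 of them higher in females and 4 lower, and 4217 probes had an unadjusted p under 0.05 where 1736.5 would be found by chance. The count is not stable: leaving out single arrays gave 9 to 65 calls. With the percentile over all probes it was 11, with 6 higher and 5 lower in females. The highest of the 27 was CUST_738_PI429851723 (contig NODE_11245, 392 bases). It was well above background in 19 of 20 females and in 0 of 20 males and was at least 11.7-fold brighter in females (adjusted p = 5.41e-06), at a log2 level of -1.60 ± 2.28 (SD, n = 20) against -6.73 ± 0.98 relative to the array's 75th percentile. CUST_6783_PI429851632 (contig NODE_25396, 468 bases) was well above background in 17 females and 0 males, at least 5.19-fold brighter in females (adjusted p = 0.000126), and the second probe of this contig, well above background in 18 females and 1 male, gave a log2 difference of 4.05 (adjusted p = 0.000203). In the other direction, CUST_14397_PI429851632 (contig NODE_48937, 361 bases) was 3.21 ± 0.60 (SE) log2 units higher in males (female minus male -3.21, adjusted p = 0.0239), well above background in 15 males and 2 females, with a second probe at -2.69 (adjusted p = 0.0862). With normexp background correction the fitted differences of CUST_738_PI429851723 and CUST_6783_PI429851632 were 2.40 (adjusted p = 0.00328) and 1.61 (adjusted p = 0.0663), below the log2 bounds of 3.55 and 2.38 behind those folds, so the bounds hold for the processed signal only. CUST_14397_PI429851632 moved to -1.15 with normexp and did not pass (adjusted p = 0.232). CUST_19711_PI429851723 (contig NODE_890465, 474 bases) was measured in all 40 mussels, and its female minus male difference was -1.63 ± 0.29 (SE; adjusted p = 0.0183).

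Apart from CUST_14397_PI429851632, the calls between the sexes were described by size. Of the 27, 10 probes of 9 contigs had a fitted difference of at least 2 log2 units, higher in females, and were well above background in a median of 17 females and 1 male. The fitted median was 3.04, but 4 of the 10 were well above background in 0 males and have only a bound, and with these at their bound the median was 2.49 and the lowest 0.50. With each male value raised to at least the lowest signal well above background on its array, the median was 1.64. A further 16 had a fitted difference under 2 log2 units, with a median size of 1.19, or 1.13 with the 2 that 1 sex did not show above background at their bound. Females were hybridised on slides 1 to 3 and males on slides 3 to 5, so that only slide 3, with 4 mussels of each sex, held both. There 8 of the 10 probes were well above background in 0 males. With male values raised in the same way, the 10 differed on slide 3 by a median of at least 2.70 and a lowest of at least 1.34 log2 units. The 16 had a median of 0.66 on slide 3 in the direction seen over all slides, or 0.63 with 3 of them at their bound. On slide 3 alone 2 probes passed the threshold (1875 at an unadjusted p under 0.05), and with slide as a block 0 did (1569 at an unadjusted p under 0.05). None of the 4 named probes was among the 2. On slide 3, CUST_738_PI429851723 was well above background in 4 females and 0 males and at least 31.9-fold brighter in females (adjusted p = 0.657), and CUST_6783_PI429851632 in 3 females and 0 males and at least 9.25-fold brighter (adjusted p = 0.826). There CUST_14397_PI429851632, well above background in 1 female and 4 males, had -3.82 (adjusted p = 0.792), and CUST_19711_PI429851723 had -0.92 (adjusted p = 0.932). In the blocked fit the fitted differences of CUST_738_PI429851723 and CUST_6783_PI429851632, which rest on males not well above background, were 7.10 ± 1.44 (SE; adjusted p = 0.335) and 4.87 ± 1.36 (adjusted p = 0.78), against 5.13 ± 0.56 and 4.17 ± 0.54 without the block. The SE was larger with the block. Whether the difference itself changed cannot be read for these 2, since they have only a bound in males. CUST_14397_PI429851632 had -3.46 ± 1.54 and CUST_19711_PI429851723 -1.15 ± 0.71 (adjusted p = 1 for both).

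**Figure D2:**
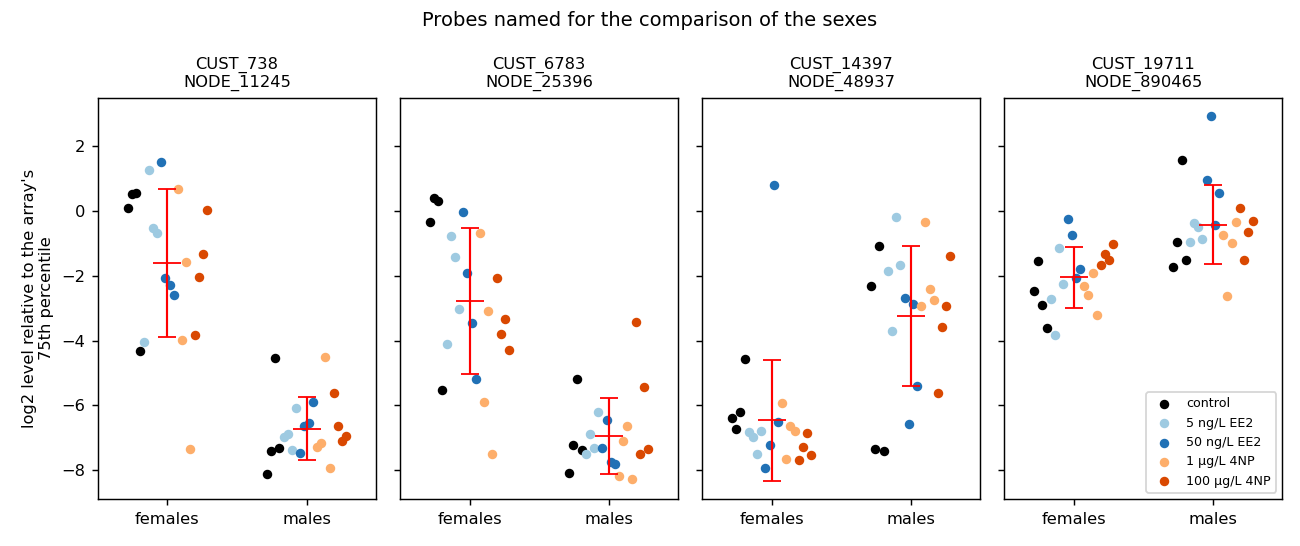
Log2 level relative to the array's 75th percentile (vertical axis) in each of 20 females and 20 males (points, coloured by treatment) for the 4 probes named for the comparison of the sexes, with red lines for the mean and SD. CUST_738_PI429851723 averaged -1.60 in females and -6.73 in males, and CUST_14397_PI429851632 averaged -6.46 in females and -3.25 in males.

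The first question about EE2 was whether 5 ng/L changed expression in the mean of both sexes, 8 mussels against 8. In limma 0 probes passed the adjusted threshold, 2135 had an unadjusted p under 0.05, and the smallest adjusted p was 0.453. The probes with the smallest p in each direction did not pass. CUST_24043_PI429851632 (contig NODE_333477) had a log2 difference of 1.54 ± 0.30 (SE; adjusted p = 0.453), with 1.27 for the second probe of the contig, and CUST_1156_PI429851723 (NODE_17574) one of 2.48 ± 0.54 (adjusted p = 0.753). In the other direction CUST_9196_PI429851723 (NODE_396268) had -3.50 ± 0.85 (adjusted p = 0.753), and CUST_35588_PI429851632 (NODE_705419), well above background in 0 of 8 exposed mussels and 6 of 8 controls, was at least 11.1-fold brighter in the controls (adjusted p = 0.753). A block for slide left 0 probes (1343 at an unadjusted p under 0.05).

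At 50 ng/L EE2, 0 of the tested probes passed over both sexes in limma, 1616 had an unadjusted p under 0.05, and the smallest adjusted p was 0.471. CUST_10569_PI429851723 (contig NODE_451737) and CUST_17949_PI429851632 (NODE_154435) had log2 differences of 1.17 ± 0.24 (SE; adjusted p = 0.471) and 0.99 ± 0.23 (adjusted p = 0.897). CUST_7210_PI429851632 (NODE_255534) was well above background in 0 of 8 exposed mussels and 5 of 8 controls, at least 1.85-fold brighter in the controls (adjusted p = 0.471). CUST_2594_PI429851632 (NODE_8380) had -0.90 ± 0.20 (adjusted p = 0.724), but the second probe of its contig had 0.09. Blocked by slide, 0 probes passed (1655 at an unadjusted p under 0.05). The direct comparison of 50 with 5 ng/L EE2 also gave 0 probes (2298 at an unadjusted p under 0.05, smallest adjusted p 0.332; with slide as a block 0 and 2638).

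At 1 µg/L 4NP, 0 probes passed over both sexes in limma, 1570 had an unadjusted p under 0.05, and the smallest adjusted p was 0.115. That value belonged to CUST_10642_PI429851723 (contig NODE_454152), well above background in 7 of 8 exposed mussels and 1 of 8 controls, with a log2 difference of 2.14 ± 0.38 (SE). CUST_26306_PI429851632 (NODE_402031) had 1.33 ± 0.30 (adjusted p = 0.763), with 1.15 for its second probe. CUST_25452_PI429851632 (NODE_378251) had -5.02 ± 1.14 (adjusted p = 0.763) and -5.05 for its second probe. CUST_32383_PI429851632 (NODE_601037), well above background in 0 of 8 exposed mussels and 6 of 8 controls, was at least 20.97-fold brighter in the controls (adjusted p = 0.763). For CUST_10642_PI429851723 and CUST_32383_PI429851632 the other exposed groups lay on the same side of the shared controls. These differences are therefore not particular to this compound or dose. When slide entered as a block, 0 probes passed (1330 at an unadjusted p under 0.05).

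At 100 µg/L 4NP, 0 probes passed over both sexes in limma, 1196 had an unadjusted p under 0.05, and the smallest adjusted p was 0.831. CUST_9398_PI429851723 (contig NODE_404894) and CUST_4554_PI429851632 (NODE_404896) had log2 differences of 1.66 ± 0.36 (SE) and 1.35 ± 0.31, both with an adjusted p of 0.831, and the second probe of NODE_404896 had 1.41. CUST_666_PI429851723 (NODE_10363) and CUST_38658_PI429851632 (NODE_913894) were each well above background in 0 of 8 exposed mussels and 5 of 8 controls, at least 16.8-fold and at least 4.34-fold brighter in the controls, also at an adjusted p of 0.831. The control levels of these last probes spread widely, with an SD of 4.47 log2 units for CUST_666_PI429851723 and 2.56 for CUST_38658_PI429851632. A block for slide left 0 probes (1192 at an unadjusted p under 0.05). The comparison of 100 with 1 µg/L 4NP gave 0 probes (1346 at an unadjusted p under 0.05, smallest adjusted p 0.777; with slide as a block 0 and 1382). The comparison of 50 ng/L EE2 with 100 µg/L 4NP, the higher dose of each compound but at unmatched doses, gave 0 probes as well (1162 at an unadjusted p under 0.05, smallest adjusted p 0.786; with slide as a block 0 and 1301).

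Within females, 4 mussels against 4, limma called 0 probes for each EE2 dose, with 1529 probes at an unadjusted p under 0.05 for 5 ng/L and 1318 for 50 ng/L. At 5 ng/L the named probes, none of which passed, were CUST_16177_PI429851723 (contig NODE_673140) at 1.77 ± 0.42 (log2 difference ± SE) and CUST_32632_PI429851632 (NODE_607978) at 1.75 ± 0.42, and below control CUST_4874_PI429851632 (NODE_675028) at -5.49 ± 1.22 and CUST_699_PI429851723 (NODE_10679) at -2.23 ± 0.50, all with an adjusted p of 1. At 50 ng/L they were CUST_10569_PI429851723 at 1.52 ± 0.33, CUST_17949_PI429851632 at 1.36 ± 0.32, CUST_2594_PI429851632 at -1.15 ± 0.28, all with an adjusted p of 1, and CUST_976_PI429851723 (NODE_14857) at -2.45 ± 0.51 (adjusted p = 0.988). The second probe of the contig of CUST_2594_PI429851632 had -0.15 (unadjusted p = 0.84). Blocked by slide, 0 probes passed at either dose (1192 and 1245 at an unadjusted p under 0.05). Within slide 1 and slide 2, the slides that held both groups, 0 passed, but each held 1 control, assumed to vary like the other groups, so these fits say little about the absence of changes. When only the 2 groups compared entered the fit, 4 probes passed for 50 ng/L.

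Within males, 1 probe passed for 5 ng/L EE2 and 0 for 50 ng/L in limma. The probe was CUST_17302_PI429851632 (contig NODE_136758, 478 bases), at a log2 level of 0.58 ± 0.44 (SD, n = 4) in exposed males and -2.31 ± 0.62 in controls, a difference of 2.89 ± 0.42 (SE; adjusted p = 0.00233). The second probe of the same contig had 0.70 (unadjusted p = 0.105). The next probes, CUST_4144_PI429851632 (NODE_42722) at 2.32 ± 0.42 (adjusted p = 0.0673) and CUST_1259_PI429851632 (NODE_390376) at -1.76 ± 0.44 (adjusted p = 0.178), did not pass, nor did CUST_26019_PI429851632 (NODE_394110), at least 1.995-fold brighter in controls (adjusted p = 0.168). The second probe of NODE_42722 went the other way, at -0.46 (unadjusted p = 0.385). The comparison had 2439 probes at an unadjusted p under 0.05. All 4 males at 5 ng/L lay on slide 5, which held no control male, so no slide gives a value of its own; with slide as a block 0 probes passed (1629 at an unadjusted p under 0.05) and CUST_17302_PI429851632 had 1.80 (adjusted p = 0.991). With only the 2 groups compared in the fit 0 probes passed, and its adjusted p was 0.164. After quantile normalization 94 probes passed, all 94 higher at 5 ng/L, and with array weights 156, of which 152 were higher.

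For 50 ng/L EE2 in males 1547 probes had an unadjusted p under 0.05. CUST_20708_PI429851632 (contig NODE_237776) and CUST_35857_PI429851632 (NODE_716432) had log2 differences of 2.71 ± 0.51 (SE; adjusted p = 0.221) and 1.99 ± 0.45 (adjusted p = 0.73). CUST_18050_PI429851723 (NODE_762641) and CUST_9877_PI429851723 (NODE_425623) were well above background in 0 of 4 exposed males and 3 of 4 controls, at least 6.19-fold (adjusted p = 0.221) and at least 1.46-fold (adjusted p = 0.502) brighter in the controls. When slide entered as a block, 0 probes passed (1496 at an unadjusted p under 0.05), and 0 passed within slide 4, where 2 exposed males met 3 controls. With only the 2 groups compared in the fit 3 passed.

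For 4NP in females, limma called 0 probes at either dose, with 1776 probes at an unadjusted p under 0.05 for 1 µg/L and 1484 for 100 µg/L. At 1 µg/L, CUST_28299_PI429851632 (contig NODE_463616) and CUST_10642_PI429851723 were well above background in 4 of 4 exposed females and 0 of 4 controls, at least 4.76-fold (adjusted p = 0.247) and at least 2.70-fold (adjusted p = 0.268) brighter. CUST_21161_PI429851632 (NODE_250859) had a log2 difference of -2.04 ± 0.39 (SE; adjusted p = 0.247), with -1.76 for its second probe, and CUST_13647_PI429851723 (NODE_570655) was at least 3.53-fold brighter in controls (adjusted p = 0.268). At 100 µg/L, CUST_15592_PI429851632 (NODE_86281) had 2.06 ± 0.42 (adjusted p = 0.298), CUST_4554_PI429851632 had 1.97 ± 0.43 (adjusted p = 0.568), CUST_23551_PI429851632 (NODE_321159) had -3.01 ± 0.61 (adjusted p = 0.298), and CUST_3849_PI429851723 (NODE_135133) was at least 7.60-fold brighter in controls (adjusted p = 0.298). A block for slide left 0 probes at either dose (1733 and 1390 at an unadjusted p under 0.05). Within slides 1, 2 and 3, 0 passed, but slides 1 and 2 held 1 control each and slide 3 held 1 exposed female of each dose. For 1 µg/L on slide 2 and 100 µg/L on slide 1 a single exposed female met the single control. Lone mussels were assumed to vary like the other groups, so these fits say little about the absence of changes. With only the 2 groups compared in the fit 8 probes passed for 1 µg/L.

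For 4NP in males, limma also called 0 probes at either dose, with 1354 probes at an unadjusted p under 0.05 for 1 µg/L and 1206 for 100 µg/L. At 1 µg/L, CUST_31563_PI429851632 (contig NODE_573654) was at least 4.02-fold brighter in exposed males, and CUST_7387_PI429851723 (NODE_308065) and CUST_36002_PI429851632 (NODE_723199) were at least 3.95-fold and at least 4.60-fold brighter in controls. CUST_17858_PI429851723 (NODE_753146) had a log2 difference of 1.36 ± 0.32 (SE), and all 4 had an adjusted p of 1. At 100 µg/L, CUST_20708_PI429851632 had 2.31 ± 0.51, CUST_1823_PI429851723 (NODE_27558) 2.89 ± 0.73, and CUST_6577_PI429851723 (NODE_269125) -2.41 ± 0.59, while CUST_20040_PI429851632 (NODE_217091) was at least 2.05-fold brighter in controls, again all with an adjusted p of 1. Blocked by slide, 0 probes passed at either dose (909 and 1193 at an unadjusted p under 0.05). Within slide 4, 0 passed for 100 µg/L with 2 exposed males against 3 controls. The fits within slide 3, with 1 control (against 1 exposed male for 100 µg/L), and within slide 4 for 1 µg/L, with 1 exposed male, also gave 0 but say little about the absence of changes. On slide 4, CUST_31563_PI429851632 was well above background in 0 of 1 exposed male and 0 of 3 controls, so that slide gives no direction for it.

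A test of the interaction asked whether any treatment acted differently in females and males. In limma 0 probes passed, 1279 had an unadjusted p under 0.05, and the smallest adjusted p was 0.741. With slide as a block 0 passed and 1227 had an unadjusted p under 0.05. For CUST_17302_PI429851632, the probe called in males at the lower EE2 dose, the male log2 difference was 2.89. In females its mean level was -0.85 ± 0.32 (SD, n = 4) at that dose and -0.64 ± 0.67 in controls, so no rise was seen. The interaction test took all treatments together, and a contrast of the sexes for this dose alone was not run. A difference between the sexes is therefore not shown by a test. The exposed males also shared a slide without control males.

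The number of mussels limits how small a change these comparisons could show. The 95% interval of a log2 difference had a median half-width of 0.83 for 8 mussels against 8, 1.17 for 4 against 4 and 0.52 for the sexes. In simulated data with the spread of these arrays, 17.9% of probes changed by 1 log2 unit, 74.6% of those changed by 2 and 87.9% of those changed by 3 were called for 50 ng/L EE2 over both sexes. For 5 ng/L EE2 in males the shares were 4.48%, 38.8% and 63.6%, and for the sexes 59.7%, 88.1% and 97.0%. With 4 mussels against 4, most changes of 1 log2 unit would therefore be missed. The simulated values were normal and independent between probes and arrays, with no slide effect, so the shares for real arrays may be lower.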

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

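The tests on slide 3, of the correlation between the contigs higher in females, of male control replicate 3 and of the second probe of a contig were chosen after the results were seen. Among 138 groups of 4 mussels examined, 13 had a mussel far from the other 3, where chance alone gives about 1 in 20. Male control replicate 3 had 16.6% of probes well above background, against 41.0% to 44.3% on the other male control arrays. CUST_24043_PI429851632 stood at -0.90 in male 5 ng/L EE2 replicate 1, CUST_2594_PI429851632 at -1.10 in female 50 ng/L EE2 replicate 3, CUST_26306_PI429851632 at -2.91 in male control replicate 1, CUST_32632_PI429851632 at -4.25 in female control replicate 2 and CUST_1259_PI429851632 at -2.71 in male control replicate 2. Some of these gaps were small: the nearest mussel of the group stood at -1.18 for CUST_24043_PI429851632 and at -1.54 for CUST_2594_PI429851632. CUST_25452_PI429851632 was at -7.71 in male 1 µg/L 4NP replicate 1. CUST_32383_PI429851632 was at -7.25 in female control replicate 2 and at -7.31 in male control replicate 4. Among the probes called between the sexes, CUST_738_PI429851723 was at -4.32 in female control replicate 4 and 1.51 in female 50 ng/L EE2 replicate 1, CUST_6783_PI429851632 at -5.54 in female control replicate 4, and CUST_14397_PI429851632 at 0.81 in female 50 ng/L EE2 replicate 3, above every male.

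The 10 probes fitted at least 2 log2 units higher in females are a pattern that slide and scan session could mimic, since most females and males lay on different slides. On slide 3, with males held at or above the lowest signal well above background, the median difference was at least 2.70. Slide 3 helped to choose these 10 probes, however. With slide as a block the fitted median was 3.94 against 3.04 without, but that fit links the sexes only through slide 3. It is thus no separate evidence, and both medians rest in part on males not well above background. The 5 such probes called without slide 3 differed there by a median of at least 3.21, which points away from slide. Of these 5, the females on slide 3 had 5, 5, 5 and 1 well above background and the males 0, 0, 1 and 0 (exact two-sided permutation p = 0.0571, n = 4 each), and their mean level, floored in every array, gave an exact p of 0.0286, the smallest possible, or 0.0571 for both after adjustment, so slide and sex cannot be told apart beyond the spread of 4 mussels. Whether male arrays were dimmer as a whole was examined for 9 of the 10. The 13330 probes of like female level on at least 17 females, as for 5 of them, were well above background in a median of 18 males. For the 2706 on 8 to 16 females, as for another 4, the median was 13 males. Only 0.03% and 0.333% were well above background in 3 or fewer males. These shares carry no weight, since they include probes of the 10, which were chosen for large differences. The limits on females and males were taken from the called probes. The medians show that male arrays as a whole reached probes of this level, but for the 9 themselves no verdict is drawn. CUST_21455_PI429851632, on 20 females and 8 males, was not covered. The 9 contigs correlated across females with a median of 0.841, so they may mark a shared state of these mussels, but whether that RNA comes from the gland or from gonad tissue cannot be told apart, because no egg or sperm gene could be named. The 16 smaller calls had a median of 0.657 on slide 3 against 1.19 over all slides (0.63 and 1.13 with undetected probes at their bound), so for these too slide and sex cannot be told apart. Other splits of the sexes within treatments argue against chance for the count as a whole, with 1 of 100 splits giving 27 calls, the real one, and at most 3 calls in any other, though these splits do not keep to slides.

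The small p-values for 5 ng/L EE2 in males may owe part of their number to slide 5. For the 100 probes with the smallest p, the shift of slide 5 against the slides of the controls was measured in the 12 males of the other exposed groups. Its median in the direction of the EE2 difference was 1.29 (quartiles 0.72 and 1.68) against a median EE2 difference of 2.82, and 95 of the 100 shifted that way, while all tested probes shifted by a median of 0.05. Slide and dose cannot be told apart here, since slide 5 held no control male. The dim array of male control replicate 3 is argued against as the cause, because 2811 probes had an unadjusted p under 0.05 without it and 2439 with it, and chance could not be excluded, since 2 of 35 splits of the 8 males called as many probes, the highest other split 1.

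A few transcripts were present in some mussels and nearly absent in others of the same group, as CUST_32383_PI429851632 shows above. In all 1647 probes, 4.74% of those tested, had a residual SD over 2 log2 units. A sequence variant under a single probe is argued against for the 879 of them with a second tested probe of the contig. Their deviations correlated with that probe with a median of 0.968. Whether the 2 probes overlap is not known, and for the rest a variant stays open. Slide is argued against as the cause for most of the 1647, since a share of 0.171 had a slide effect at an unadjusted p under 0.05 in either sex. Of all tested probes 0.175 did, so slide effects were about as common here as elsewhere and slide stays open for some of the 1647. Array brightness is argued against, with a median absolute correlation of 0.130 with the percent of probes well above background. Differences between mussels in genes carried, diet, parasites or physiological state stay open and were not tested.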

How the results depend on the processing

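The percentile over all probes, the fit without the 2 dim arrays and the fits within slides were chosen after seeing the data. So was the set of 8005 probes behind the percentile of the main fit. The counts for 100 µg/L 4NP in females and in males and over both sexes, for 50 ng/L EE2 and 1 µg/L 4NP over both sexes, for 5 ng/L EE2 in females, for 1 µg/L 4NP in males, for the doses of each compound, for the compounds and for the interaction stayed at 0 under every alternative other than leaving out single arrays. The count between the sexes, 27, moved to 4 with normexp, 12 without the filter, 1 among probes well above background on all arrays (fewer probes tested), 49 with array weights, 0 with slide as a block, 11 with the percentile over all probes and 2 within slide 3 with treatments ignored. The split of these calls was 22 higher and 8 lower in females after quantile normalization, and 6 and 5 with the percentile over all probes, against 23 and 4. The count for 5 ng/L EE2 in males, 1, moved to 94 after quantile normalization, 70 in the authors' table, 156 with array weights, 4 with the percentile over all probes, 6 without the 2 dim arrays, and 0 with slide as a block or with only the groups compared. For 1 µg/L 4NP in females 0 moved to 1 in the authors' table, 1 among probes well above background on all arrays, 2 with array weights and 8 with only the groups compared. For 50 ng/L EE2, 0 moved to 4 in females and 3 in males with only the groups compared and to 1 in males in the authors' table, and for 5 ng/L EE2 over both sexes to 1 among probes well above background on all arrays. The cause of these moves was not tested, beyond the smaller number of probes named.

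Replicate numbers were not taken to pair the mussels. The deviations of same-numbered females and males of a treatment correlated between -0.133 and 0.0886 over 20 pairs, with 0 above 0.1, and those of same-numbered mussels of 1 sex across treatments between -0.232 and 0.209 over 80 pairs, with 6 above 0.1. With a replicate block the count between the sexes was 5, of which 5 were higher and 0 lower in females, without CUST_14397_PI429851632 (adjusted p = 0.0576) and CUST_19711_PI429851723 (adjusted p = 0.0569), whose differences stayed at -3.21 and -1.63. The block gave 1 for 50 ng/L EE2 in males, and the count stayed at 1 for 5 ng/L EE2 in males, and at 0 for the other comparisons. As a random block (consensus correlation 0.0207), same numbers left the comparisons over both sexes at 0.

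Leaving out each array in turn gave 9 to 65 calls between the sexes and 1 to 10 for 5 ng/L EE2 in males. The range was 0 to 2 for 100 µg/L 4NP in females, 0 to 1 for 5 ng/L EE2 in females, 50 ng/L EE2 in males, 1 µg/L 4NP in females, in males and over both sexes, 50 ng/L EE2 over both sexes and 50 against 5 ng/L EE2, and 0 to 0 for the others. Between the sexes the count was 65 without male 100 µg/L 4NP replicate 2 and 16 without replicate 4; 10, 17 and 47 without male 1 µg/L 4NP replicates 4, 3 and 2; 10 without male 50 ng/L EE2 replicate 3; 14 without male 5 ng/L EE2 replicate 4; and 16, 12 and 41 without male controls 1, 2 and 4. It was 9 and 12 without female controls 2 and 3, 17 and 12 without female 5 ng/L EE2 replicates 2 and 3, 9 without female 50 ng/L EE2 replicate 2, and 17, 13 and 11 without female 100 µg/L 4NP replicates 1, 2 and 3. For 5 ng/L EE2 in males it was 2, 10 and 2 without control 1, control 4 and exposed replicate 2. Of 1273 values of named probes under other settings, only CUST_31563_PI429851632 reversed, at -0.34 within slide 4, where it was well above background in 0 of 1 exposed male and 0 of 3 controls, so the sign has no weight. CUST_738_PI429851723 and CUST_6783_PI429851632 passed without any 1 of the 40 arrays, and CUST_14397_PI429851632 passed in 37 of these fits. With normexp, CUST_738_PI429851723 fell to 2.40 and passed, while CUST_6783_PI429851632 (1.61, adjusted p = 0.0663) and CUST_14397_PI429851632 (-1.15, adjusted p = 0.232) did not pass, the last 2 over adjusted p of 3e-05 to 0.826 and 0.0183 to 1 across their alternatives. The gene list alternatives were not run, since no list matched a probe, and for the sexes the fit of only the groups compared is the same fit. Signal over background limits the dim probes, since the 75th percentile of signal ranged from 28.6 to 239.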

Other observations

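The tests of the score of the contigs higher in females were chosen after the scores were seen. A score was made as the mean log2 level of the 9 contigs fitted at least 2 log2 units higher in females, with probes not well above background at their measured value, so that low scores have no order. It ran from -6.82 to -0.32 in females, and males are left out because most of these probes were not well above background in them. Among female controls 3 mussels lay at or above -1.49 and replicate 4 at -6.15. The mean was -2.15 ± 2.72 (SD, n = 4) in female controls, -3.08 ± 1.38 at 5 ng/L EE2, -3.48 ± 1.65 at 50 ng/L EE2, -4.34 ± 2.35 at 1 µg/L 4NP and -3.84 ± 0.54 at 100 µg/L 4NP. That exposure lowers the score was a hypothesis that these mussels did not settle. Exact two-sided permutation tests of the 70 assignments gave p of 0.543, 0.429, 0.286 and 0.229 (n = 4 each, smallest possible 0.0286), and 0.543 for each after adjustment over the 4 tests. After adjustment over 4 tests, even a complete separation from controls in 1 treatment could not have passed, so the tests leave a change open.

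Probes well above background in 1 mussel alone were uneven between mussels. Of all probes 5746 were well above background on a single array, with a median of 70 per array. Female 5 ng/L EE2 replicate 2 held 1101 of them, female 100 µg/L 4NP replicate 4 held 688 and male 1 µg/L 4NP replicate 1 held 346. In the first of these, 680 had a second probe on the array for the same contig, and 51.3% of these second probes were well above background in that mussel, against 5.19% on the other arrays. That array was the brightest, with 53.3% of all probes well above background, so 51.3% is near its share over all probes, and the low share elsewhere follows in part from choosing probes absent there. In female 100 µg/L 4NP replicate 4 it was 17.9% of 391 second probes, and in male 1 µg/L 4NP replicate 1 30.4% of 214. Over all probes those arrays had 47.2% and 50.8%. On both, most second probes thus did not show the contig. These are values with no tested explanation, and they lie outside the comparisons because such probes did not enter them.

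A response shared by the sexes was tested as a hypothesis, by correlating female with male log2 differences from control across probes, with no control shared. The correlation was 0.0231 for 5 ng/L EE2, 0.0382 for 50 ng/L EE2, 0.0209 for 1 µg/L 4NP and -0.0174 for 100 µg/L 4NP. With treatment and control labels redrawn within each sex, the highest of the other 99 values were 0.101, 0.105, 0.163 and 0.127, and 28, 16, 31 and 61 of the 100 values were as high as the real one. No shared response was seen, but a weak one stays open, since the median SE of a log2 difference in 1 sex was 0.57. The share of the sum of squares over all probes between the 5 treatments was 20.6% in females and 20.5% in males, where 10000 redrawn labels gave medians of 21.01% and 20.95% (p = 0.696 and 0.654, permutation tests). The real groups were thus separated no more than the median of random groups, which does not exclude changes in few transcripts.

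Other splits of the same mussels were counted for each comparison, on the number of probes at an unadjusted p under 0.05. For the sexes, 2 of 100 splits reached the real 4217, the highest other being 5230, so a chance draw of mussels is argued against. The splits ignore slide, which follows sex except on slide 3, and with slide as a block the count was 1569, so they say nothing of slide. For no other comparison could chance be excluded. Over both sexes, 32 of 100 splits reached the real count for 5 ng/L EE2 (2135, highest other 4333), 40 for 50 ng/L EE2 (1616, 3129), 51 for 1 µg/L 4NP (1570, 2847) and 80 for 100 µg/L 4NP (1196, 4738). For the doses of EE2 it was 9 (2298, 3365), for those of 4NP 69 (1346, 4701), for the compounds 81 (1162, 3062) and for the interaction 77 (1279, 2744). In females, out of 35 splits, 26 reached it for 5 ng/L EE2 (1529, 4049), 11 for 50 ng/L EE2 (1318, 2546), 2 for 1 µg/L 4NP (1776, 2773) and 12 for 100 µg/L 4NP (1484, 2278). In males the numbers were 10 for 5 ng/L EE2 (2439, 3092), 25 for 50 ng/L EE2 (1547, 3748), 31 for 1 µg/L 4NP (1354, 5562) and 34 for 100 µg/L 4NP (1206, 6160). Some splits of males called many probes where the real groups called 0, up to 287 for 1 µg/L 4NP and 213 for 100 µg/L 4NP. Both put male control replicate 3, at 16.6% of probes well above background, on the same side as the dimmest exposed male, at 31.7% and 25.5%. In both, 3 of the 4 arrays on that side also lay on slide 4. Such splits point to a structure of the samples other than treatment, and whether it is brightness or slide was not tested.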
